A study of Mus musculus with 18 samples.

How the data were processed

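RNA of whole mouse embryos at embryonic day 9.5 was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 1 embryo per array and 18 arrays. Biotin-labelled cRNA was made from 6 ug of total RNA per array. Per the labels, the embryos had a mixed 129SvEv and C57Bl/6 background and carried 9 genotypes built from 4 Tbx1 alleles, with 2 biological replicates each. The deposited values are log2 probe set summaries made with affy and RMA, per the submitters' processing notes. RMA corrects the background of each array, equalises the distributions over arrays by quantile normalization and summarises the probes of a probe set by median polish. The versions of affy and RMA and any filter are not given in the sources used here. The values were used as deposited, without rescaling and without a filter on dim probe sets. RMA values carry no detection call, so a low signal cannot be told from background, and the number of arrays limits the precision of every value.

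The table held 45037 probe sets and no value of array controls. The annotation gave 1 gene symbol to 34945 of them, which stand for 18193 genes. It gave several genes to 932 probe sets and none to 9160. Gene IDs of 34741 probe sets were matched to the RefSeq genes of mouse assembly GRCm38.p6, which changed 0 symbols. That assembly was used only for names and for the order of genes along chromosomes. Where 1 value per gene was needed, the probe set with the highest mean over the 18 arrays was taken, among those with a single symbol.

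Differences were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes without an intensity trend, and all tests were two-sided. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets. Each genotype was compared with WT in a fit with 9 genotype means, which leaves 9 residual degrees of freedom, with 3.63 prior degrees of freedom. The same fit compared -/- with the mean of the 4 other genotypes that lack a wild-type allele, and gave a moderated F-test of any difference between genotypes. A fit with 3 means, by the number of wild-type alleles (10 arrays with 0, 6 with 1 and 2 with 2), left 15 residual degrees of freedom. An additive fit with the numbers of Neo2, Neo and null alleles as 3 terms left 14. A moderated F-test asked whether genotypes depart from that additive fit, and a regression on the Tbx1 signal tested the other 45036 probe sets. SE is limma's moderated standard error, and SD is given for values per genotype. Adjusted p-values are limma's unless another test is named.

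The 27 gene lists covered pharyngeal endoderm and pouches, second heart field, cranial mesoderm and branchiomeric muscle, otic vesicle and placodes, neural crest, cardiomyocytes, endothelium, primitive erythroid cells, macrophages and platelets, visceral yolk sac endoderm, placenta and decidua, neurons and neural progenitors, presomitic mesoderm and somites, posterior Hox genes, limb bud, FGF signalling, the retinoic acid, hedgehog, BMP and canonical Wnt pathways, genes linked to Tbx1 in the literature, chromosomal neighbours of Tbx1, p53 targets, hypoxia response, immediate early genes, cell cycle and sex markers. The sex markers (Xist and Y-linked genes) served to call the sex of each embryo, and the other 26 lists were tested with camera at a preset correlation of 0.01, with p adjusted over lists within a comparison. Camera with an estimated correlation and fry were run beside it. A list score is the mean over its genes of the deviation from each gene's mean over the 18 arrays. An early embryo list and a list of maternal uterus and decidua genes were added for tests in the closing section.

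The genes named in the text follow a rule. For -/- against WT, -/- against the 4 other genotypes without a wild-type allele and the comparisons by number of wild-type alleles, the rule takes up to 10 genes per direction with the largest change past the threshold. Where fewer than 5 pass in a direction, it takes those with the smallest p up to 5, with values only. For other tests it takes the 3 genes with the smallest p per direction, or 5 for F-tests, and for gene lists up to 4 members with the smallest p. Tbx1 is always named and the sex markers never. Genes named outside the rule are said to have been chosen after their values were seen. The comparisons, lists, rule and most alternatives were fixed before the data were examined.

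The analysis was tested on simulated data with 45037 probe sets, of which 200 were changed. In -/- against WT, 19.4% of the changes of 0.5 on the log2 scale were recovered, 76.1% of those of 1 and 97.0% of those of 2, with 11 false calls. With 0 against 1 wild-type allele the shares were 76.1%, 98.5% and 98.5%, with 11 false calls, and per Neo allele 86.6%, 98.5% and 98.5%, with 8. A simulated shift of 0.3 in the cell cycle list, among 18193 genes, was found at an adjusted p of 1.2e-49, with 0 other lists called. Simulated noise was independent between probe sets, whereas the estimated correlation in the data was 0.57 for erythroid genes (0 against 1 wild-type allele). The simulation therefore does not measure false list calls among genes that vary together. It also gave all arrays of a probe set the same noise. In the data the difference between replicates had an SD over probe sets of 0.41 in -/- and 0.53 in +/-, against 0.18 to 0.25 in the other genotypes. The recovered shares and false calls for -/- against WT may therefore be too favourable.

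The alternatives were medians subtracted per array, a further quantile normalization, leaving out the dimmer probe sets, a variance trend with intensity, embryo sex or the posterior Hox score as a covariate, the replicate number as a block, other codings of the comparisons, other list tests and leaving out each array in turn. Leaving out +/- replicate 1 and -/- replicate 1 together, leaving out both Neo2/Neo2 arrays, and array weights from limma were chosen after seeing the data. Correlations over arrays were tested with 100000 permutations. Scan dates and litters are not given in the sources used here, so neither was modelled. Unnamed probe sets were tested and counted, but are not interpreted.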

Results

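Transcript levels were measured in 18 whole mouse embryos of embryonic day 9.5, in a series that varies the dosage of Tbx1. Tbx1 encodes a T-box transcription factor of the pharyngeal apparatus and is a main gene of DiGeorge syndrome. The 9 genotypes combine the wild-type allele (+), the alleles Neo2 and Neo, which keep part of the activity of Tbx1, and a null allele (-). Each genotype had 2 embryos. WT holds 2 wild-type alleles, Neo2/+, Neo/+ and +/- hold 1, and Neo2/Neo2, Neo2/Neo, Neo2/-, Neo/Neo and -/- hold 0. The log2 values of an array had medians between 5.73 and 5.94, and the number of arrays limits the precision. By Xist and Y-linked genes, 9 embryos were female and 9 male. Both WT and both -/- embryos were female, both Neo2/Neo2 and both Neo/Neo embryos were male, and the other genotypes had 1 of each. 

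Replicate 1 of +/- and replicate 1 of -/- stood apart from the other arrays. The +/- array lay at -100.6 on principal component 1, which held 26.3% of the variance, and its median correlation with the other arrays was 0.975. There Fubp1, Zmynd11 and Pcbp1, which encode nuclear and RNA-binding proteins, differed by -5.87, -5.36 and -4.24 (log2) from their means on the other arrays. The -/- array lay at 73.2 on principal component 3 (14.1%), with a median correlation of 0.985. On it the nuclear RNA Malat1 had a signal of 8.29 against 12.30 on the other arrays, the microtubule protein gene Map1b 6.97 against 10.73, and Prap1, a gene of secretory epithelia, 10.74 against 4.42. These genes were chosen after their values were seen. Counts below are also given without these 2 arrays, an alternative chosen after seeing the data.

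**Figure D1:**
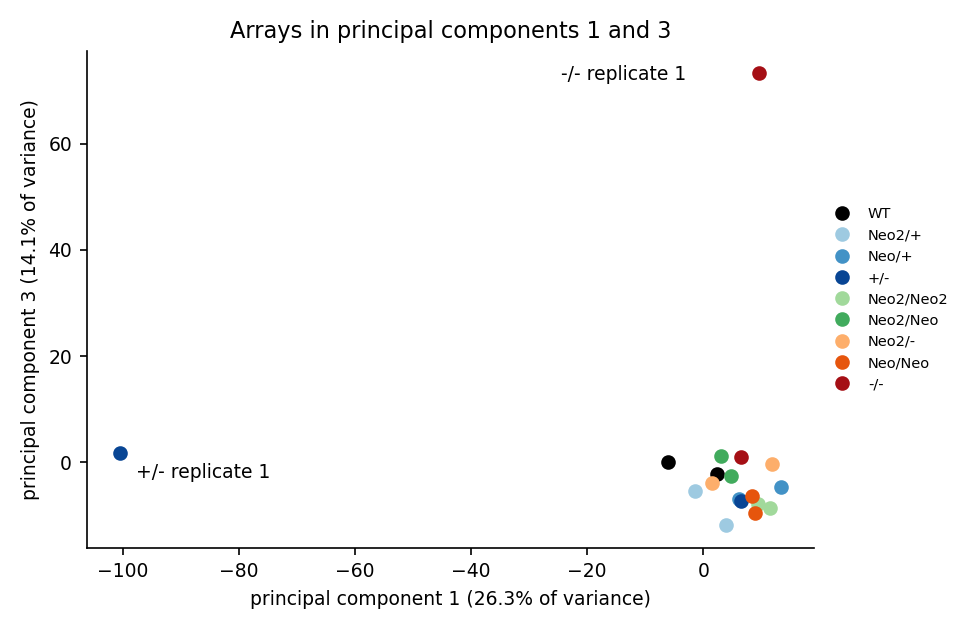
Each point is 1 array, placed by its scores on principal components 1 and 3 (26.3% and 14.1% of the variance) and coloured by genotype. Replicate 1 of +/- lies at -100.6 on component 1 and replicate 1 of -/- at 73.2 on component 3, away from the other arrays.

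The Tbx1 signal shows how far each genotype lowers the transcript, read at the only probe set with that symbol. WT embryos had a signal of 6.59 ± 0.06 (log2, SD, n = 2), and Neo/Neo and -/- embryos had 5.12 ± 0.11 and 5.07 ± 0.13. Tbx1 fell by 1.47 in Neo/Neo (2.77-fold; adjusted p = 0.0029) and by 1.52 in -/- (2.86-fold; adjusted p = 0.0030), each with an SE of 0.14. Neo2/Neo had 5.66 ± 0.02 and Neo2/- had 5.71 ± 0.13, differences of -0.92 and -0.88 whose adjusted p-values were 0.189 and 0.420. That adjustment is over all probe sets, and limma's unadjusted p-values for Tbx1 were 1.9e-05 and 3.2e-05. For Neo2/+, Neo/+ and +/- the unadjusted p-values were 0.767, 0.0589 and 0.144. The arrays labelled Neo2/Neo2 had 6.62 ± 0.00, a difference of 0.03 (adjusted p = 0.967). They lay above Neo2/Neo and Neo2/-, which hold 1 Neo2 allele beside a Neo or null allele. Since Neo/Neo and -/- were lower still, that order alone does not put the labels in doubt. Whether the WT level of these 2 embryos reflects the Neo2 allele or a wrong label was not tested, and the labels were kept. Among the heterozygotes the differences were -0.04 in Neo2/+, -0.29 in Neo/+ and -0.22 in +/-, with adjusted p-values of 1.00, 0.687 and 0.555, and the +/- replicates were at 6.61 and 6.13.

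Tbx1 was called in Neo/Neo and in -/- in 17 of the 18 fits that left out 1 array. In the remaining fit the difference stayed about as large and just missed the threshold: -1.39 without replicate 1 of Neo/Neo (adjusted p = 0.0512) and -1.43 without replicate 1 of -/- (adjusted p = 0.0524). Without both arrays that stood apart, the adjusted p was 0.0056 in Neo2/Neo and 0.0276 in Neo2/-, and without either +/- array alone it was 0.0151 and 0.0396. Without +/- replicate 2 the +/- difference became 0.02, that of Neo2/+ became 0.00 without WT replicate 2 or Neo2/+ replicate 2, and that of Neo2/Neo2 became -0.01 without WT replicate 1. Whether the signal in -/- is background or a transcript that remains was not tested, and the position of this probe set relative to the deleted part of the gene is not given in the sources used here, so the folds need not measure the loss of transcript.

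**Figure D2:**
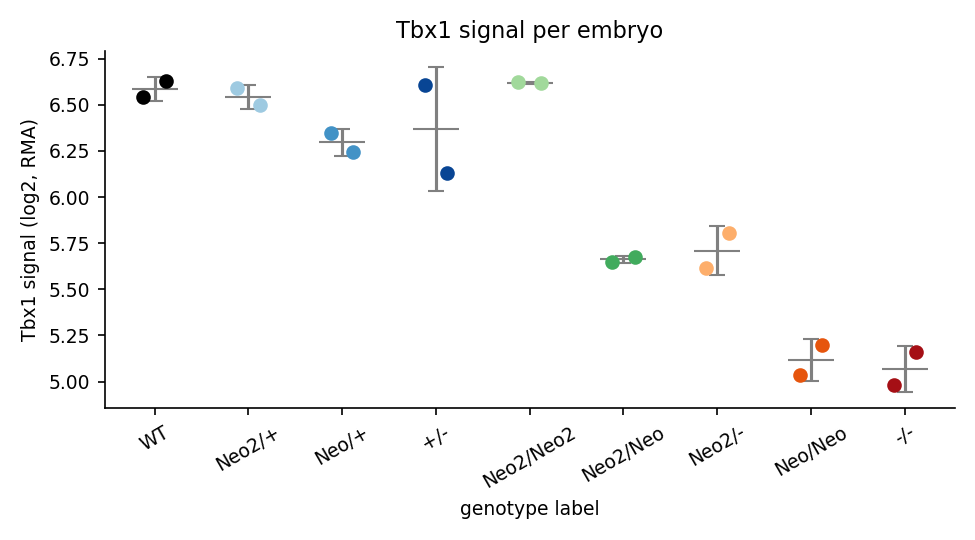
Tbx1 signal (log2, RMA) of each embryo as points, by genotype, with the mean as a dash and the SD of 2 embryos as bars. WT embryos lie at 6.59 on average, Neo2/Neo and Neo2/- at 5.66 and 5.71, and Neo/Neo and -/- at 5.12 and 5.07.

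Embryos without Tbx1 were compared with WT to find the genes that respond to its complete loss. Tbx1 fell, and so did Fos, an immediate early transcription factor gene, by 0.99 (SE 0.14, n = 2 against 2, adjusted p = 0.0367). Apela, which encodes a secreted ligand of the apelin receptor, rose by 0.99 (SE 0.15, 1.98-fold, adjusted p = 0.0479), and the transcript A930024E05Rik rose by 0.75 (SE 0.10, adjusted p = 0.0335). These 3 calls passed narrowly: each was lost without WT replicate 1 (adjusted p = 0.237, 0.341 and 0.237) and without any array of Neo2/+, Neo/+, Neo2/Neo2, Neo2/Neo or Neo/Neo. A second, dim probe set of Apela had 0.13. The called one did not follow the Tbx1 signal over the series. Its mean was 6.57 in Neo/Neo, where Tbx1 was about as low as in -/-, against 6.46 in WT and 7.45 in -/-. It was highest, at 7.51, on the arrays labelled Neo2/Neo2, where Tbx1 was at the WT level. The Apela rise in -/- need not be a response to the loss of Tbx1. Fos was below WT (5.84) in every mutant genotype, at 4.78 to 5.35, and A930024E05Rik was at 6.77 in Neo/Neo. Genes next in rank that did not pass were Mns1 (0.98), which acts in motile cilia, Cyria (0.79) and Ccdc160 (0.81) among the higher ones, and Zfhx3 (-0.90), a homeodomain transcription factor gene, Scarf2 (-0.69) and the kinesin gene Kif15 (-0.54) among the lower ones, with adjusted p-values of 0.0702 to 0.0764. Other calls, chosen after their values were seen, were on dimmer probe sets of their genes, with differences of -2.47 for Lsm8 (SE 0.24), -1.24 for Ep400, 0.95 for Tex9 and 1.05 for Dcun1d1. The brightest probe sets of these genes did not pass. That of Ep400 had -0.58 (SE 0.17) and that of Dcun1d1 0.70 (SE 0.18), in the direction of the call, while those of Lsm8 and Tex9 had 0.17 and 0.16. Further dimmer calls were on Actb (-0.67), Jmjd4 (-1.40) and Snrpb2 (0.97). The brightest probe sets of Actb, Jmjd4 and Snrpb2 had 0.01, 0.18 and 0.22 and did not pass.

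In all, limma called 14 probe sets in -/- against WT, 6 higher and 8 lower, of which 11 carried a gene name, and 6806 had an unadjusted p under 0.05. Without the 2 arrays that stood apart it called 65, 20 higher and 45 lower. The count was 0 without -/- replicate 1, 5121 without -/- replicate 2, 2 without WT replicate 1 and 94 without WT replicate 2. It was 54 without either +/- array, 7 without either Neo2/Neo2 array, 6 without any single array of Neo2/+, Neo/+ or Neo2/Neo, and 4 without either Neo/Neo array.

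Complete loss was then set against the 4 other genotypes that lack a wild-type allele but hold a Neo or Neo2 allele. Mns1 rose by 0.88 (SE 0.13, n = 2 against 8, adjusted p = 0.0453) and A930024E05Rik rose by 0.58 (SE 0.08). Zfhx3 fell by 0.92 (SE 0.12, adjusted p = 0.0389), Aplp1, a neuronal relative of the amyloid precursor protein, fell by 0.86 (SE 0.12), the atypical cadherin gene Fat4 fell by 0.76 (SE 0.11), the scavenger receptor gene Scarf2 fell by 0.71 (SE 0.09) and the kinase gene Sbk1 fell by 0.69 (SE 0.10). The comparison is with a mean of genotypes that differ: Fat4 was at 7.76 in -/- but lower still on the arrays labelled Neo2/Neo2 (7.63), with Neo2/Neo at 9.06 and Neo/Neo at 8.94. Zfhx3, Aplp1, Scarf2 and Sbk1 were lowest in -/- (8.53, 7.40, 7.60 and 9.95). They were next lowest on the arrays labelled Neo2/Neo2 (8.85, 7.67, 8.07 and 10.26) and highest in Neo2/Neo (9.87, 8.81, 8.52 and 11.02). Tbx1 was at the WT level on the Neo2/Neo2 arrays, so these falls need not be responses to its complete loss. No other probe set of these genes passed: those of Zfhx3 had from -0.86 to 0.08, those of Scarf2 -0.12 and -0.17, and those of Aplp1, Fat4 and Sbk1 had -0.42, -0.59 and -0.52. Mcm8, Dtd1 and Zfp39 had differences of 0.56, 0.46 and 0.82 that did not pass (adjusted p = 0.0505 each), and Tbx1 had -0.71 (SE 0.11, adjusted p = 0.0505). Calls on dimmer probe sets, named after their values were seen, had differences of -1.05 for Birc6, -1.35 for Lsm8, -0.90 for Ep400 and -0.74 for Rbmx, where the brightest probe sets of these genes had -0.15, 0.23, -0.53 and -0.21 and did not pass. The Lsm8 probe set was lower in Neo/Neo (3.91) than in -/- (4.08).

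The comparison gave 11 calls, 2 higher and 9 lower, with 7889 at an unadjusted p under 0.05, and 21 calls without the 2 arrays that stood apart, 3 higher and 18 lower. Both -/- embryos were female and 6 of the 8 others male, and all calls were lost (0) with embryo sex as a covariate, as they were with array weights. Without the Neo2/Neo2 arrays, an alternative chosen after seeing the data, there were 434. Leaving out single arrays gave 9 without Neo2/- replicate 1, 148 without Neo2/- replicate 2, 403 without either +/- array, 23 without Neo2/Neo2 replicate 2, 1 without Neo2/Neo replicate 2, 6 without -/- replicate 1 and 6598 without -/- replicate 2. It gave 0 without any other array.

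Homozygosity for Neo was compared with WT to ask what follows from the lower dosage that this allele leaves. Besides Tbx1, Gm6958 fell by 5.88 (SE 0.59, n = 2 against 2, adjusted p = 0.0034) and 2610507I01Rik fell by 1.55 (SE 0.18). Fn3krp, which encodes a kinase that repairs glycated proteins, rose by 1.63 (SE 0.24, adjusted p = 0.0278), the chromatin protein gene Arid4a rose by 0.69 (SE 0.10) and the zinc finger gene Zfp467 rose by 0.73 (SE 0.11). These values are those of the brightest probe set, and no other probe set of these genes passed: the others had -2.67 for Gm6958, -0.41 for 2610507I01Rik, 0.03 and 0.11 for Arid4a and 0.39 and 0.11 for Zfp467. Calls on dimmer probe sets, chosen after their values were seen, had differences of -3.38 (SE 0.38) for the RNA-binding protein gene Tia1, -2.71 for Lztfl1, a gene of ciliary transport, -2.05 for the dynein regulator gene Ndel1, -1.93 for the peroxiredoxin gene Prdx2, 1.93 for the kinase gene Mapk8 and 1.70 for the securin gene Pttg1. The brightest probe sets of these genes did not pass: Pttg1 had 1.32, but Tia1 had 0.11, Lztfl1 -0.01, Ndel1 0.12, Prdx2 0.03 and Mapk8 -0.26, so for these 5 the calls need not mean that the genes changed. Among other genes with a dimmer call, the brightest probe sets of Csf2rb (-1.91, adjusted p = 0.0097) and Lars2 (-1.51, adjusted p = 0.0148) moved alike and passed. Those of Abcb10 (-1.11) and Mettl7a1 (-0.95) moved alike and did not pass. Dimmer calls on Lsm8, Zfp945, Pde10a, Jade1 and Elk3 were -2.64, -1.92, 0.72, 0.82 and 0.99. Their brightest probe sets had -0.055, 0.30, -0.10, 0.19 and 0.32 and did not pass, so these calls too need not mean that the genes changed. In Neo/+ embryos, which keep a wild-type allele, the same probe sets had differences from WT of -3.77 for Tia1, -2.76 for Lztfl1, -2.06 for Ndel1 and -2.04 for Prdx2, all of which passed. Those of Mapk8 (7.34 against 6.15 in WT) and Pttg1 (10.97 against 9.22) were not called there.

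limma called 37 probe sets in Neo/Neo, 9 higher and 28 lower, of which 29 were named, with 3158 at an unadjusted p under 0.05. Without the 2 arrays that stood apart there were 136 calls, 60 higher and 76 lower. Both Neo/Neo embryos were male and both WT embryos female, and 17 calls were left with embryo sex as a covariate. The count was 0 without Neo/Neo replicate 1, 4 without Neo/Neo replicate 2, 10 without WT replicate 1 and 66 without either -/- array.

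**Figure D3:**
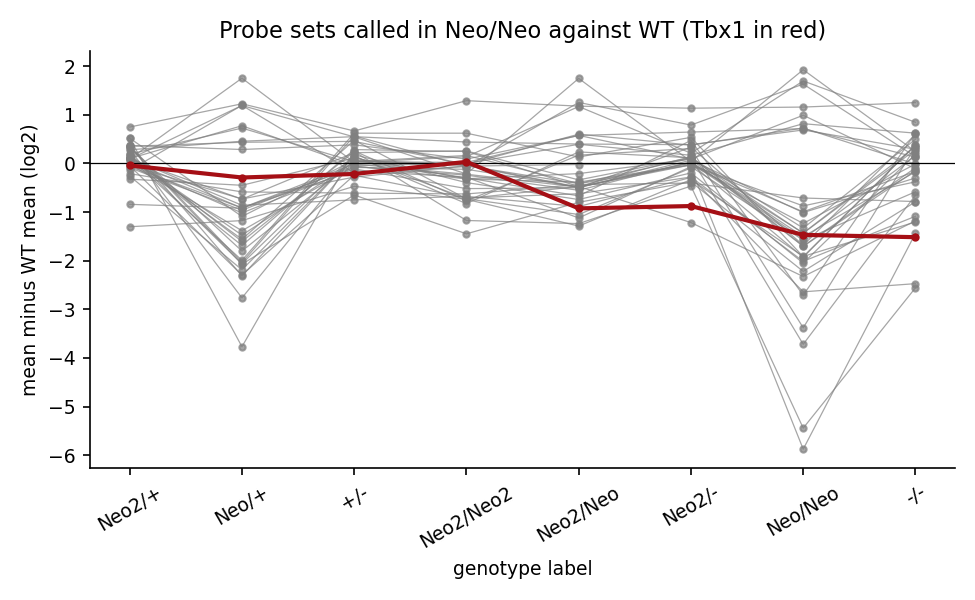
Each line is 1 of the 37 probe sets called in Neo/Neo against WT, with its genotype mean minus the WT mean (log2) for the 8 mutant genotypes and Tbx1 in red. The lines leave 0 in Neo/+ as well as in Neo/Neo, with the largest fall, Gm6958, at -5.88 in Neo/Neo, while Tbx1 is lowest in Neo/Neo and -/- at -1.47 and -1.52.

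The other genotypes were compared with WT to follow the series from mild to strong alleles. In Neo/+ embryos 2010315B03Rik fell by 1.80 (SE 0.23, n = 2 against 2, adjusted p = 0.0185), Ang, the gene of the ribonuclease angiogenin, fell by 1.47 (SE 0.20), 1500015A07Rik fell by 1.51 (SE 0.22) and B9d1, a gene of the ciliary transition zone, rose by 0.78 (SE 0.11, adjusted p = 0.0406). Dimmer probe sets of Ang had -0.67 and -0.13. Pttg1 (1.35) and 2810021J22Rik (0.61) did not pass. In +/- embryos the leading genes, none of which passed, were Apela (0.78), Arid4a (0.55) and Slc35d1 (0.54), a nucleotide sugar transporter gene, on the higher side and 2610005L07Rik (-0.85), Padi3 (-0.68) and Ceacam11 (-0.48) on the lower. In Neo2/+ they were Snapc5 (0.69), Mb21d2 (0.58), Tmco6 (0.62), Fos (-0.998), the cytokine receptor gene Csf2rb (-1.30) and the dynein gene Dnah5 (-0.57), again without a call.

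Without a wild-type allele the leading named genes did not pass either. On the arrays labelled Neo2/Neo2 they were Apela (1.05), Mb21d2 (0.95), Ablim1 (0.72), Rpl27a (-0.89), Fat4 (-0.83) and Pag1 (-0.82), with adjusted p-values from 0.0770 to 0.167. In Neo2/Neo they were the adhesion genes Edil3 (1.10) and Chl1 (1.11), Abtb2 (0.77), Csf2rb (-1.29), Tbx1 and Sfmbt2 (-0.88). In Neo2/- they were the transcription factor gene En2 (0.57), Ahrr (0.56), Rab39b (0.64), Fos (-1.06), Tbx1 and Gm12596 (-0.57). Each of these 3 genotypes had 1 call, on a probe set that the annotation leaves without a gene and that is singled out after its values were seen. Its mean was 6.41 in WT, between 7.07 and 7.70 in every mutant genotype, and it was called in 6 of them, with adjusted p-values of 0.0111 in Neo2/Neo2, 0.0308 in Neo2/Neo and 0.0458 in Neo2/-.

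limma called 14 probe sets in Neo/+ (2 higher and 12 lower), and 0 in Neo2/+ and in +/-, with 3314, 2932 and 5277 at an unadjusted p under 0.05. For Neo2/Neo2, Neo2/Neo and Neo2/- those numbers were 5234, 3027 and 2830. Without the 2 arrays that stood apart the calls were 68 in Neo/+, 0 in Neo2/+, 1 in +/-, 911 in Neo2/Neo2 (477 higher and 434 lower), 23 in Neo2/Neo and 2 in Neo2/-. Leaving out WT replicate 2 gave 21 in Neo2/+, 28 in Neo/+, 21 in +/-, 40 in Neo2/Neo2, 21 in Neo2/Neo and 17 in Neo2/-. Leaving out WT replicate 1 gave 1, 3, 1, 1, 0 and 0 in the same order.

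Leaving out either Neo/+ array ended all calls in Neo/+ (0), while either +/- array gave 36, either -/- array 32, either Neo2/Neo2 array 22 and either Neo/Neo array 8. In +/- the count was 5066 without +/- replicate 2 and 1 without either -/- array. In Neo2/Neo2 it was 0 without its replicate 2, 6 without its replicate 1, 45 without either -/- array, 12 without either +/- array and 3 without either Neo2/- array. In Neo2/Neo it was 5 without either -/- array, 6 without either +/- array, 2 without either Neo2/- array and 1 without Neo2/Neo replicate 2, and in Neo2/- it was 2 without either +/- array and 1 without either -/- array. For these 2 genotypes, leaving out any other array except WT replicate 2 gave 0.

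Grouping the embryos by the number of wild-type alleles asks for effects shared across genotypes. With 0 against 1 wild-type allele (n = 10 against 6), no gene passed. The genes with the smallest p were Cirbp (0.34, SE 0.09), a cold-inducible RNA-binding protein gene, Arrdc2 (0.30), Depp1 (0.26), 9330133O14Rik (0.29) and 6030468B19Rik (0.18) on the higher side and Snhg7 (-0.29, SE 0.06), Zfp692 (-0.25), the helicase gene Ddx11 (-0.24), Ang3 (-0.23) and Mettl2 (-0.17) on the lower, each with an adjusted p of 0.888. Tbx1 itself was 5.64 ± 0.59 (SD, n = 10) against 6.40 ± 0.19 (n = 6), a difference of -0.77 (SE 0.22, unadjusted p = 0.0029, adjusted p = 0.888). In a fit without the Neo2/Neo2 arrays, an alternative chosen after seeing the data, Tbx1 had -1.01 (SE 0.13, adjusted p = 0.0485) and was the only call. limma called 0 probe sets, with 2038 at an unadjusted p under 0.05.

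Against WT embryos, those without a wild-type allele (n = 10 against 2) differed in 1 probe set, the unnamed one described above, which rose by 1.20 (SE 0.14, adjusted p = 0.0041). The leading named genes did not pass: Fos (-0.82, SE 0.16), Oc90 (-0.69, SE 0.14), which encodes an otoconial protein of the otic vesicle, 2410004P03Rik (-0.58), Baalc (-0.43) and Ceacam11 (-0.41) on the lower side and Mb21d2 (0.64), Samsn1 (0.44), Atxn3 (0.43), Taf9b (0.35) and Ctns (0.32) on the higher, with adjusted p-values from 0.239 to 0.365. Without WT replicate 2 Fos had -1.05 and passed (adjusted p = 0.0428). Tbx1 had -0.95 (SE 0.34, unadjusted p = 0.0108, adjusted p = 0.645). Unadjusted p was under 0.05 for 2792 probe sets, and the count of calls was 0 without WT replicate 1 and 100 without WT replicate 2.

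Embryos with 1 wild-type allele, the state closest to the human syndrome, were compared with WT (n = 6 against 2). Psg28, a pregnancy-specific glycoprotein gene, had the largest difference among the leading genes (-1.34). The 2 WT embryos differed in it, with an SD of 1.14, and the difference was -0.53 without WT replicate 1 and -2.14 without WT replicate 2. It was followed by Fos (-0.88), Baalc (-0.46), Ceacam11 (-0.44) and 6030468B19Rik (-0.41), and on the higher side Mb21d2 (0.65), Tm9sf1 (0.58), Dtwd2 (0.56), the interferon-inducible gene Ifi202b (0.41) and the cystinosin gene Ctns (0.35). Dtwd2 was 0.29 without WT replicate 1 and 0.84 without WT replicate 2. None passed (adjusted p = 0.320 to 0.539), but without WT replicate 2 Psg28, Fos and Dtwd2 did (adjusted p = 2.9e-04, 0.0422 and 0.0182), and Tbx1 had -0.18 (SE 0.35, adjusted p = 0.980). limma called 0 probe sets, with 2720 at an unadjusted p under 0.05, and 75 without WT replicate 2.

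The additive fit gives an average effect per allele of each kind, without assuming its activity. The estimates for Tbx1 were -0.83 per Neo allele (SE 0.10, n = 18 arrays, adjusted p = 0.0033), -0.83 per null allele (SE 0.10, adjusted p = 0.0107) and -0.20 per Neo2 allele (SE 0.10, adjusted p = 0.920). These averages need not be what each allele does. Beside a wild-type allele, 1 Neo or null allele came with -0.29 or -0.22, and the homozygotes came with -1.47 and -1.52. The F-test for departure of Tbx1 from additivity had an unadjusted p of 0.0018 but an adjusted p of 0.231, so it was not called. Per Neo allele Fn3krp rose by 0.99 (SE 0.15), Pttg1 rose by 0.77 (SE 0.13), the calpain gene Capn7 rose by 0.35 (SE 0.05), 2610507I01Rik fell by 0.69 (SE 0.08) and Zfp39 fell by 0.62 (SE 0.08). Of their other probe sets 1 passed, of Pttg1 (0.96), and the rest had 0.48 for Pttg1, 0.26 and 0.27 for Capn7, -0.24 for 2610507I01Rik and -0.11 for Zfp39. Leading genes without a call were the signalling gene Wnt5a (0.23), Mex3d (0.20), Porcn (0.18), Oc90 (-0.34), A930001A20Rik (-0.17) and Tbc1d2 (-0.16) per Neo2 allele, and Gimap6 (0.27), Agpat5 (0.25), ccdc198 (0.44), Rpl27a (-0.38) and Aak1 (-0.25) per null allele.

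limma called 31 probe sets per Neo allele (10 higher and 21 lower), 1 per null allele (Tbx1) and 0 per Neo2 allele, with 3155, 4864 and 2161 at an unadjusted p under 0.05. Without the 2 arrays that stood apart the counts were 76, 1 and 1. Per Neo allele, single arrays gave 3 without Neo/Neo replicate 1, 9 without Neo/Neo replicate 2, 7 and 5 without WT replicates 1 and 2, 18 and 19 without Neo2/+ replicates 1 and 2, 52 without Neo/+ replicate 1, 16 without +/- replicate 2, 19 without Neo2/Neo replicate 1 and 48 without -/- replicate 1. Per null allele the count was 0 without either -/- array and 2 without Neo2/+ replicate 2 or either Neo2/- array.

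A test for any difference between genotypes called 124 probe sets. Taking the brightest probe set per gene, the smallest p-values were those of Tbx1 (adjusted p = 0.0017), 2010315B03Rik (0.0038), Fat4 and Ang (0.0061) and Zfp39 (0.0067), while dimmer probe sets of Zfp945, Tia1, Lsm8, Lztfl1 and Ndel1 also ranked above 2010315B03Rik, and 6158 had an unadjusted p under 0.05. It called 1247 without the 2 arrays that stood apart, and single arrays moved it to 21 (without Neo/Neo replicate 1), 477 and 3051 (without -/- replicates 1 and 2), and 190 and 4777 (without +/- replicates 1 and 2). It was 28 without Neo/Neo or Neo2/Neo replicate 2, 30 without Neo2/Neo replicate 1, 39 and 41 without Neo2/+ replicates 1 and 2, 43 and 46 without those of Neo/+, and 75 and 57 without those of Neo2/Neo2. limma called 0 departures from additivity, with 5076 at an unadjusted p under 0.05; the smallest p-values, by the brightest probe set per gene, were those of Fat4, Apela, Zfhx3, the apolipoprotein gene Apoh and the homeobox gene Otp, and Tbx1 had an adjusted p of 0.231. That count was 725 without the 2 arrays that stood apart, 129 and 1688 without -/- replicates 1 and 2, 4 and 4392 without those of +/-, 2 and 9 without those of WT, 3 without Neo2/Neo2 replicate 1 and 1 without any array of Neo2/Neo or Neo2/-. In the regression on the Tbx1 signal, limma called 0 of 45036 probe sets, with 3938 at an unadjusted p under 0.05. The leading slopes per log2 unit of Tbx1 were those of Fam171a1 (0.30), the glutamate receptor gene Gria3 (0.21), Tut1 (0.20), Fam120aos (-0.28), Atp6v1g1 (-0.26) and the transcription factor gene Crem (-0.22), with an adjusted p of 0.553 each. The count was 1 without Neo2/- replicate 2 and 2 without -/- replicate 2.

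Gene lists fixed in advance ask whether cell types or pathways of the embryo shifted. With 0 against 1 wild-type allele, the primitive erythroid genes were shifted up by camera, with 17 of 19 members above 0, a mean of 0.28 and an adjusted p of 1.1e-07 (adjusted p = 0.662 with an estimated correlation). Among them were the haem enzyme genes Blvrb (0.56, SE 0.21) and Fech (0.28), the transcription factor gene Gata1 (0.34) and the anion exchanger gene Slc4a1 (0.61, SE 0.28), none of which passed; Blvrb was at 0.34 without +/- replicate 1. Immediate early genes were shifted up, 17 of 21 above 0 with a mean of 0.10 (adjusted p = 0.0018, and adjusted p = 0.306 with an estimated correlation), with Klf4 at 0.30 and Zfp36 at 0.21. Yolk sac endoderm genes were shifted up, 15 of 23 above 0 with a mean of 0.18 (adjusted p = 0.0181, and adjusted p = 0.468 with an estimated correlation), among them the plasma protein genes Ttr (0.79, SE 0.30), Alb (0.77), Apoa2 (0.61) and Apoa1 (0.35). Macrophage and platelet genes were shifted up, 14 of 15 above 0 with a mean of 0.13 (adjusted p = 0.0125, and adjusted p = 0.970 with an estimated correlation), with Mrc1 at 0.43, Adgre1 at 0.20 and Cd68 at -0.24.

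The other 22 lists were not shifted in this comparison. The adjusted p was 0.996 for the second heart field, cranial mesoderm, limb bud, FGF, retinoic acid, hedgehog and cell cycle lists, 0.873 for the BMP list, 0.802 for cardiomyocytes, 0.779 for the chromosomal neighbours of Tbx1 and for p53 targets, and 0.638 for somites. It was 0.516 for neural crest, placenta, posterior Hox genes and genes linked to Tbx1, 0.320 for the Wnt list, 0.301 for pharyngeal endoderm, 0.281 for endothelium, 0.138 for the otic list and for neurons, and 0.101 for hypoxia. Adjusted over the list alone, 1 member passed in this comparison, Wnt8a of the Wnt list, at -0.26 (SE 0.07). The macrophage and platelet list did not pass without either Neo2/Neo array or without replicate 1 of Neo2/+, Neo/+, Neo/Neo or -/-, with means from 0.08 to 0.13 and adjusted p-values from 0.0589 to 0.0868, nor with the dimmer probe sets left out (mean 0.11, adjusted p = 0.105). The yolk sac list did not pass without either Neo2/Neo array, Neo/+ replicate 2 or Neo/Neo replicate 1, with means from 0.13 to 0.16 and adjusted p-values from 0.0541 to 0.103.

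With 0 against 2 wild-type alleles, p53 targets were shifted up, 18 of 20 above 0 with a mean of 0.16 (adjusted p = 9.0e-04, adjusted p = 0.0576 with an estimated correlation and 0.0168 by fry). Its leading members were the apoptosis genes Bbc3 (0.30, SE 0.07), Perp (0.33, SE 0.10) and Pmaip1 (0.57, SE 0.25). The 2 WT embryos had the lowest p53 scores of all 18 arrays (-0.15 and -0.11), so the shift rests on them. Genotypes without a wild-type allele had mean scores of 0.0046 to 0.0675. The heterozygotes had -0.05 in Neo2/+, -0.02 in Neo/+ and 0.08 in +/- (0.13 and 0.02 on its arrays). Erythroid genes were shifted down, 19 of 19 below 0 with a mean of -0.21 (adjusted p = 9.0e-04, and adjusted p = 0.992 with an estimated correlation), with the membrane skeleton genes Sptb at -0.36 and Epb42 at -0.39 and the haem synthesis gene Alas2 at -0.44; without WT replicate 1 Sptb was at -0.11, and without WT replicate 2 at -0.61. Second heart field genes were shifted up, 20 of 23 above 0 with a mean of 0.14 (adjusted p = 0.0290, and adjusted p = 0.992 with an estimated correlation), with Osr1 at 0.40 (SE 0.11), Gata4 at 0.37, Wnt5a at 0.24 and Sema3c at 0.20, of which Osr1 was at 0.21 and Wnt5a at 0.15 without WT replicate 1. Adjusted over the list alone, 1 member passed in each of 3 lists: Oc90, Bbc3 and Fos. The other 23 lists had adjusted p-values from 0.0512 to 0.984.

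In that comparison the second heart field list no longer passed without WT replicate 1 (mean 0.10, adjusted p = 0.213), Neo2/Neo2 replicate 2 (0.12, adjusted p = 0.0514) or Neo/Neo replicate 2 (0.14, adjusted p = 0.0542), with sex as a covariate (0.10, adjusted p = 0.311) or after a further quantile normalization (0.12, adjusted p = 0.129). It did not pass either with the posterior Hox score as a covariate (0.14, adjusted p = 0.0634) or with the dimmer probe sets left out (0.17, adjusted p = 0.0529). The mean was about the same or larger in these settings. Camera sets a list against the other genes, so the mean alone does not show whether the shift stayed. The erythroid list did not pass without WT replicate 1 (-0.14, adjusted p = 0.117). Without the Neo2/Neo2 arrays neither list passed (0.10, adjusted p = 0.0877, and -0.13, adjusted p = 0.0595), which left 1 list shifted, p53 targets.

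In -/- against WT, erythroid genes were shifted down, 18 of 19 below 0 with a mean of -0.30 (adjusted p = 0.0022, and adjusted p = 0.898 with an estimated correlation), with Slc4a1 at -0.98 (SE 0.35), Sptb at -0.60, Epb42 at -0.54 and the embryonic globin gene Hbb-y at -0.21. Neuronal genes were shifted down, 23 of 29 below 0 with a mean of -0.32 (adjusted p = 0.0028, and adjusted p = 0.898 with an estimated correlation), among them the intermediate filament gene Ina (-0.96, SE 0.37), the RNA-binding protein gene Elavl3 (-0.93, SE 0.29), Neurod1 (-0.67) and Dll3 (-0.57). Hedgehog genes were shifted down, 14 of 18 below 0 with a mean of -0.19 (adjusted p = 0.0109, and adjusted p = 0.898 with an estimated correlation), with Gli2 at -0.68 (SE 0.25), Shh at -0.46 (SE 0.16), Gas1 at -0.29 and Gli3 at -0.22. Fos was the only list member that passed over all genes. Adjusted over the list alone, the members that passed were Oc90 (-0.76, SE 0.16), the receptor genes Fgfr3 (-0.57) and Fgfr2 (-0.37), Flrt3 (0.42), Nr2f1 (-0.45) in 2 lists, Kmt2c (-0.59) and Fos. The other 23 lists had adjusted p-values from 0.0600 to 0.924.

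The erythroid scores of the -/- embryos differed by more than the shift, with an SD of 0.65 (n = 2), and without -/- replicate 2 the mean of the list was 0.16 (adjusted p = 0.343). The neuronal mean without that array was -0.0032 (adjusted p = 0.671), and without WT replicate 2 the neuronal and hedgehog lists did not pass, with means of -0.26 and -0.16 (adjusted p = 0.147 each). The hedgehog mean was -0.07 without -/- replicate 1 (adjusted p = 0.264) and without both arrays that stood apart (adjusted p = 0.0767), and the erythroid mean -0.12 with the posterior Hox score as a covariate (adjusted p = 0.103). Single members moved as well: without -/- replicate 1 Gli2 was at -0.28, Shh at -0.18, Gas1 at -0.07, Gli3 at -0.11, Dll3 at -0.15 and Fgfr2 at -0.21, and without -/- replicate 2 Slc4a1 was at -0.49, Sptb at -0.32, Epb42 at -0.19 and Ina at -0.46. Without the 2 arrays that stood apart, 12 lists were shifted instead of 3 in -/- against WT and 7 instead of 3 with 0 against 2 wild-type alleles. Fry called 0 lists in -/- against WT and with 0 against 1 wild-type allele, and 1 with 0 against 2.

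The neuronal score varied between embryos of the whole series. Its mean was -0.57 on the arrays labelled Neo2/Neo2 (SD 0.06, n = 2), 0.11 in WT (SD 0.07) and 0.64 in Neo2/Neo (SD 0.04). Over the 18 arrays it ran against an early embryo list of pluripotency and early progenitor genes, with a Pearson r of -0.791 (permutation p = 1.1e-04, adjusted 4.4e-04 over 4 relations) and a Spearman rho of -0.915 (permutation p = 1.0e-05, the smallest that the permutations can give). Without the 2 arrays farthest from the median of the early embryo list, r was -0.945.

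**Figure D4:**
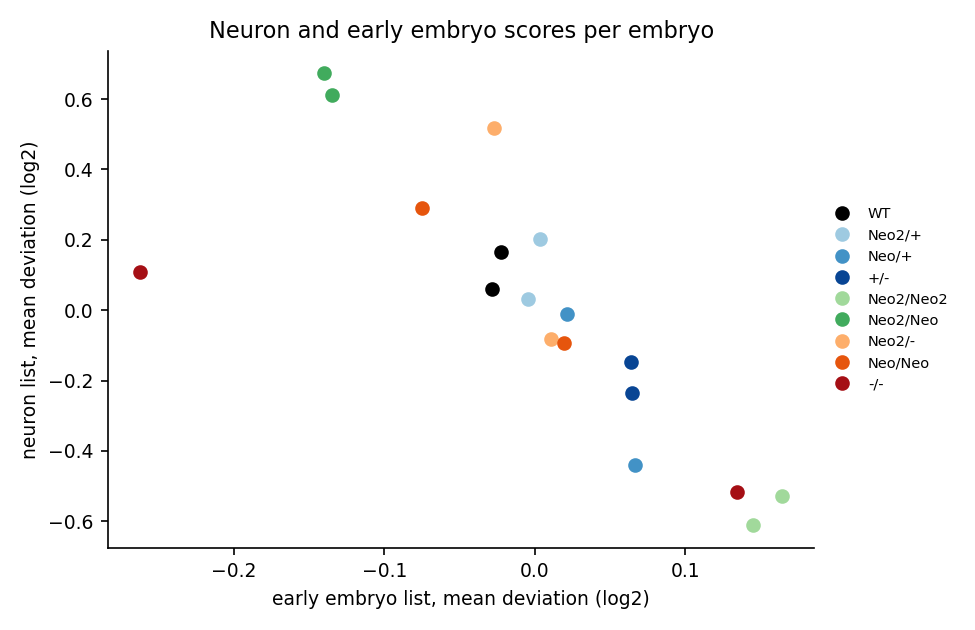
Each point is 1 embryo, with the score of the early embryo list on the horizontal axis and that of the neuron list on the vertical axis (mean deviation, log2), coloured by genotype. Embryos high in the early list are low in the neuron list, with a Pearson r of -0.791 over 18 arrays.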

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

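The tests of loss of Tbx1 product, of sequence variants and of Tbx1 dosage were chosen only after the result was seen, and the others were written down before.

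Among the probe sets called in Neo/Neo against WT were 36 other than Tbx1. Their median ratio of the Neo/+ to the Neo/Neo difference was 0.83 (95% bootstrap interval 0.66 to 0.97). The same ratio was 0.36 for Neo2/Neo and 0.03 for Neo2/-. Sharing the 2 WT arrays alone gave an unchanged genotype a median ratio of 0.06 (-0.01 to 0.12 over 50 simulations). There the 36 smallest p-values of each simulation were taken. Over all called probe sets, a median of 912 per simulation, it was 0.16 (0.13 to 0.19). The simulations called far more probe sets than the data, so the ratio of an unchanged genotype is not settled. Loss of Tbx1 product as the whole cause is argued against by -/- embryos, in which Tbx1 was as low and the median ratio was 0.146 (0.0085 to 0.356). Stretches of chromosome from another strain carried with the Neo line are a candidate explanation: 15 of the 25 placed member genes had another member within 200 genes, such as Pttg1, Zfp39, 2610507I01Rik and Ndel1 on chromosome 11, where random lists had a median of 9 and a 95th percentile of 14, though the highest of 10000 had 22 and 0 members lay near Tbx1. Sequence variants under single probe sets cannot be told apart from changed transcripts, since the other probe sets of 22 member genes had a median ratio of 0.170 (14 of the 22 under 0.25) with an interval (0.0208 to 0.271) that crosses the bound of 0.25. The background is labelled as mixed, and the strain of origin of each region was not tested.

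The neuron score varied among genotypes of like Tbx1 signal: the arrays labelled Neo2/Neo2 lay -0.68 from WT with a Tbx1 difference of 0.03, Neo2/Neo lay 0.53 and Neo2/- 0.11 from WT, and Neo/Neo -0.01 and -/- -0.32 (SE 0.25 each). Tbx1 dosage as the source had little to go on, with a Pearson r of -0.299 over 18 arrays (permutation p = 0.228, rho -0.342, and r = -0.237 without the 2 farthest arrays), but it stays open, since the Neo2/Neo2 difference was -2.71 times its SE and short of the 3 asked of its size. Embryo age at collection may account for the spread, since the early embryo list fell as the neuron score rose (r = -0.791, permutation p = 1.1e-04, and -0.945 without the 2 farthest arrays). The erythroid score ran with the neuron score (r = 0.622, permutation p = 0.0065, adjusted p = 0.0130) and the posterior Hox score did not (r = 0.02, permutation p = 0.939). Somite counts are not used here, and a delay that belongs to a genotype cannot be told apart from litters of different age.

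Replicate 1 of -/- and replicate 1 of +/- lay far from the other arrays. For the -/- array, noise of single probe sets is argued against, since the deviations of the 2 brightest probe sets per gene ran together (r = 0.562 across 9010 genes, which are not independent, the second highest of the 18 arrays). For the +/- array such noise is a candidate explanation, with the lowest r of the 18 arrays, 0.125. Maternal uterine tissue, by 27 measured genes of 30 listed, stays open for both. The -/- array lay at percentile 84.88 of random lists, with a mean deviation of 0.07 against a 95th percentile of 0.11. With 1 gene left out in turn its percentile ran from 62.01 to 95.13, the highest without Alpl (-0.81). The +/- array lay at percentile 12.53, but there 18 of the 27 genes were above 0. Krt18 (-2.21) pulled its mean down (percentile 34.23 without that gene), and the interval of the mean (-0.23 to 0.14) holds the random median of 0.09. A biological explanation was not tested, since the other embryo of each genotype lay elsewhere.

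In 54 groups, the Tbx1 signal or a list score was searched for an array that lay apart. Each group held the 10 arrays with 0 wild-type alleles or the 6 with 1. An array was flagged where its gap to the nearest other, as a share of the whole range, exceeded the 95% critical value, and 11 were found. Chance flags about 1 in 20 independent groups. These groups share arrays, and some lists share genes, so the 11 cannot be measured against that rate. Among the 10 arrays with 0 wild-type alleles, -/- replicate 1 lay apart by this gap as the lowest in 8 lists: pharyngeal endoderm with a gap share of 0.639 (score -0.26), otic vesicle 0.584 (-0.27), neural crest 0.477 (-0.21), endothelium 0.749 (-0.40), limb bud 0.492 (-0.22), hedgehog 0.602 (-0.30), BMP 0.631 (-0.20) and genes linked to Tbx1 0.631 (-0.27). Among the 6 arrays with 1 wild-type allele, +/- replicate 1 lay apart as the highest in the otic list, with 0.646 (0.19), and the lowest in the cell cycle list, with 0.843 (-0.39). Neo/+ replicate 1 lay apart as the highest in the erythroid list, with 0.639 (0.07).

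With 0 against 1 wild-type allele the real count of called probe sets was 0. Every split reaches that count (100 of 100 splits of the 16 arrays), so other splits cannot test it. The highest other had 1942, and what sets that split apart was not tested. For lists chance cannot be excluded: 61 of 100 splits had as many as the real 4, with 15 as the highest other. When whole genotypes were regrouped, 44 of 56 splits had as many as the real 4, with 13 as the highest other.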

How the results depend on the processing

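Leaving out +/- replicate 1 and -/- replicate 1 together, leaving out both Neo2/Neo2 arrays, and array weights were chosen after seeing the data; the other alternatives were planned. For the changes below the cause was not tested. Where an array left out leaves a genotype with 1 array, that array is assumed to vary like the other groups. The alternative with other Tbx1 probe sets was not run, since there is 1. What limits these results is the signal over background, which RMA values do not give, and 2 embryos per genotype.

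Without both arrays that stood apart the counts of called probe sets were 68 in Neo/+, 1 in +/-, 911 in Neo2/Neo2, 23 in Neo2/Neo, 2 in Neo2/-, 136 in Neo/Neo, 65 in -/-, 21 in -/- against the other genotypes without a wild-type allele, 1 per Neo2 allele, 76 per Neo allele, 1247 for any genotype and 725 for departure from additivity. Shifted lists were 7 with 0 against 2 wild-type alleles and 12 in -/- against WT, and Tbx1 passed in Neo2/Neo (-0.92, adjusted p = 0.0056) and Neo2/- (-0.88, adjusted p = 0.0276). With array weights, which were lowest for the +/- (0.30) and -/- (0.351) arrays, the counts were 55 in Neo/+, 12 in Neo2/Neo2, 11 in Neo2/Neo, 119 in Neo/Neo, 1 in -/-, 0 in -/- against the others, 88 per Neo allele, 1335 for any genotype and 1100 for departure, and Tbx1 passed in Neo2/Neo (-0.92, adjusted p = 0.0077). Without both Neo2/Neo2 arrays they were 1 with 0 against 1 wild-type allele and 434 in -/- against the others, with 1 list shifted with 0 against 2.

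With embryo sex as a covariate the counts were 1 in Neo2/+, 8 in Neo/+, 0 in Neo2/-, 17 in Neo/Neo, 6 in -/-, 0 in -/- against the others, 11 per Neo allele and 57 for any genotype. With the posterior Hox score they were 9 in Neo/+, 0 in Neo2/Neo, 0 in Neo2/-, 115 in -/-, 568 in -/- against the others, 19 per Neo allele, 3 per null allele and 18 for any genotype, with 5 lists in -/-. A further quantile normalization gave 27 in Neo/+ and 70 in -/- against the others. Medians subtracted gave 84 there and 6 lists in -/-. Without the dimmer probe sets there were 7 in Neo2/Neo2, 7 in -/- and 355 in -/- against the others. A variance trend gave 0 in Neo2/-. Only the 4 arrays of -/- and WT gave 0. Contrasts of genotype means gave 1 with 0 against 1 wild-type allele and 5 with 0 against 2. The mean over the probe sets of a gene gave 5 lists with 0 against 2. An estimated correlation left 0 lists in each of the 3 comparisons, and fry gave 0, 1 and 0.

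The replicate number as a block gave 2 in Neo2/Neo2, 0 in Neo2/- and 8 in -/-. The numbers do not pair embryos: replicate differences of 36 genotype combinations correlated at -0.26 to 0.19 across genes, with a median of 0.04.

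Leaving out single arrays gave counts of 0 to 21 in Neo2/+, 0 to 36 in Neo/+, 0 to 5066 in +/-, 0 to 45 in Neo2/Neo2, 0 to 21 in Neo2/Neo, 0 to 17 in Neo2/-, 0 to 66 in Neo/Neo, 0 to 5121 in -/-, 0 to 6598 in -/- against the others, 0 to 100 with 0 against 2 wild-type alleles, 0 to 75 with 1 against 2, 3 to 52 per Neo allele, 0 to 2 per null allele, 0 to 2 with the Tbx1 signal, 21 to 4777 for any genotype and 0 to 4392 for departure. Lists ranged from 2 to 6 with 0 against 1, 2 to 9 with 0 against 2 and 1 to 12 in -/-. The Tbx1 difference ranged from -0.0884 to 0.0041 in Neo2/+, -0.4547 to 0.0207 in +/-, -0.0126 to 0.078 in Neo2/Neo2, -0.97 to -0.88 in Neo2/Neo, -0.97 to -0.78 in Neo2/-, -1.55 to -1.39 in Neo/Neo and -1.61 to -1.43 in -/-. The erythroid mean in -/- was 0.158 without -/- replicate 2 and -0.7626 without -/- replicate 1.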

Other observations

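The comparisons of the arrays labelled Neo2/Neo2 with WT in the fit without +/- replicate 1 and -/- replicate 1 were tests chosen only after the result was seen. Among the genes called higher in that fit, chosen after their values were seen, were the homeobox genes Cdx4, which rose by 2.17 (SE 0.24, n = 2 against 2, adjusted p = 0.0153), Cdx2 by 1.52 (SE 0.20) and Nkx1-2 by 2.25 (SE 0.29), Hoxb1 by 1.39 (SE 0.16), the T-box gene Tbx6 by 0.99 (SE 0.20) and Fgf17 by 0.89 (SE 0.10). Lin28a, an RNA-binding protein gene of early progenitors, rose by 1.56 (SE 0.27, adjusted p = 0.0290). In the canonical Wnt list, which holds Cdx4 and Cdx2, 5 of 23 members rose, among them Sp5 (1.16) and Lef1 (0.50). That list was shifted up by camera (adjusted p = 4.4e-04, and adjusted p = 0.279 with an estimated correlation) and by fry (adjusted p = 0.0070). In the second heart field list 4 of 23 members rose (Gata4, Wnt5a, Wnt11 and Hoxb1), with an adjusted p of 2.1e-04, and adjusted p = 0.279 with an estimated correlation.

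Neuronal genes were lower on the same arrays. In the neuron list 6 of 29 members fell, among them Nhlh2 (-1.84, SE 0.34), the neurofilament genes Nefm (-1.78, SE 0.29) and Nefl (-1.45, SE 0.32) and the tubulin gene Tubb3 (-1.24, SE 0.27), with an adjusted p of 3.6e-12 for the list and adjusted p = 0.344 with an estimated correlation. In the erythroid list 4 of 19 fell: Hemgn (-1.39, SE 0.19), Alas2 (-0.996), Epb42 (-0.99) and Slc4a1 (-0.82) (list adjusted p = 6.1e-14, and adjusted p = 0.279 with an estimated correlation). Fry called the erythroid and second heart field lists in this fit but not the neuron list. Both Neo2/Neo2 embryos were male and both WT embryos female. With all 18 arrays the named genes of this comparison did not pass.

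Fos had a mean of 5.84 in WT and between 4.78 and 5.35 in the 8 mutant genotypes. Oc90 had 5.27 in WT and between 4.49 and 4.99 in the mutants. These comparisons share the 2 WT embryos.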
